A study of Mus musculus with 24 samples.

How the data were processed

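Epididymal adipose tissue and liver of 12 mice were measured on 24 Affymetrix arrays, 3 per group of tissue, genotype and diet. The deposited values are linear MAS5 signals in intensity units, which the authors scaled to a common trimmed mean per the labels' protocols, and the trimmed mean of each array was 100.03 to 100.05. The version of the MAS5 software is not given in the sources used here. Values ranged from 0.01 to 21952 and array medians from 13.5 to 25.8. No column of the matrix was left out, and no further scaling was applied. Detection calls were not used here.

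Of 45101 probe sets 64 were controls and were left out. A table of probe set annotations gave a single gene symbol to 34958 and several to 932, and 9160 others had none. The brightest probe set stood for each of 18194 genes. In each tissue values under the 10th percentile of all its values (1.08 in adipose tissue, 1.10 in liver) were raised to it, and log2 was taken. Genes were tested if their mean reached that of the median probe set (19.3 and 13.0 intensity units), which left 11613 in adipose tissue, 11125 in liver and 10119 in both.

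Group means were fitted by limma 3.58.1 in R 4.3.3, per tissue, with a variance trend (8 residual degrees of freedom, prior degrees of freedom 3.16 in adipose tissue and 5.24 in liver). The contrasts were KO versus WT on each diet, HFD versus ND in each genotype, their interaction and the genotype effect averaged over the diets, and a joint fit compared the genotype effect on HFD between tissues. Every adjusted p is a Benjamini-Hochberg value from limma or from its list tests, and genes under 0.05 were called. Lists of genes by cell type or pathway with at least 5 tested genes were tested by camera with a fixed correlation of 0.01, and again by camera with the correlation estimated from the data and by fry. Their members were also adjusted over the list alone. Genes named in the text were Ffar4, the 8 largest rises and 8 largest falls of KO versus WT on HFD and of HFD versus ND in WT among called genes with non-overlapping groups, 4 and 4 for other comparisons, up to 4 members of smallest p per list, and up to 20 genes called in both tissues. For interactions and averages, which compare more than 2 groups, non-overlap was not required. Further genes are given as values. These rules, the lists, the tests and most alternatives were set before the data were examined.

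Where a gene's dimmer group averaged under the filter, the change is given as at least the ratio of the brighter mean to the filter level, a rule chosen after the values were seen, and its fitted log2 difference depends on the floor. Because the same mouse gave both tissues, pairing was checked: the deviations of a mouse's arrays from their group means correlated at 0.0335 to 0.125 between tissues, above 0.1 in 4 of 12 mice. Alternatives were quantile normalization, no filter, no floor, the mean of a gene's probe sets, the compared groups' arrays alone, leaving out 1 array, and mouse as a replicate block. The procedure was tested on simulated data with 200 changed genes. Noise was drawn independently for each probe set around 1 mean for all groups of a tissue. The procedure recovered 69.8 to 98.3% of 4-fold, 30.8 to 83.9% of 2-fold and 9.09 to 56.7% of 1.5-fold changes over 13 comparisons, the lowest in the adipose interaction. Of its calls 1.71 to 9.89% were false. Genes in the data can vary together, and 6423 of 11613 were called for diet in WT fat, so these rates need not hold there. Chromosomes and gene order came from a GRCm38.p6 gene table.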

Results

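Gene expression was measured on Affymetrix arrays in epididymal adipose tissue and liver of 12 mice, 6 per diet, that either carried or lacked GPR120. This G protein-coupled receptor responds to long-chain fatty acids and is encoded by Ffar4. The title of the series asks whether GPR120 takes part in obesity induced by a high-fat diet (HFD), so knockout (KO) mice were compared with wild-type (WT) mice on HFD and on normal diet (ND), and the diets were compared within each genotype. Each of the 8 groups held 3 arrays, and the same mouse gave both tissues, so the 24 arrays came from 12 animals. The labels give a mixed 129/Sv and C57BL/6 background for the mice. Array medians lay between 13.5 and 25.8 intensity units after the authors' scaling, and within a group the arrays correlated with Spearman's rho of 0.889 to 0.964. The number of arrays limits the precision of every value. Differences are given as log2 ± SE from the limma fit of each tissue.

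Ffar4 was read by 1 probe set. In adipose tissue its signal was 26.7 ± 3.68 (SD, n = 3) in KO mice on HFD and 131.6 ± 37.4 in WT mice on HFD, and no KO array (23.1 to 30.5) reached the lowest WT array (97.3). The log2 difference of -2.27 ± 0.21 corresponded to 4.83-fold (adjusted p = 0.000215). On ND the signals were 34.5 ± 1.06 in KO and 64.6 ± 8.07 in WT mice, a log2 difference of -0.90 that did not pass (adjusted p = 0.111). WT adipose tissue held more Ffar4 on HFD than on ND (log2 0.99, adjusted p = 0.00223), and the diet effect differed between genotypes (interaction log2 -1.37, adjusted p = 0.0175). In liver the gene lay below the filter and ran the other way, with signals of 15.9 ± 2.42 in KO and 1.12 ± 0.543 in WT mice on HFD (adjusted p = 0.0336 among all unfiltered genes). On ND the liver signals were 27.1 ± 8.43 in KO and 6.88 ± 9.04 in WT mice (adjusted p = 0.0946), the WT mean resting on mouse 687 at 17.3. Where this probe set lies relative to the deleted part of the gene is not given in the sources used here, so a signal left in KO arrays decides nothing about the labels.

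**Figure D1:**
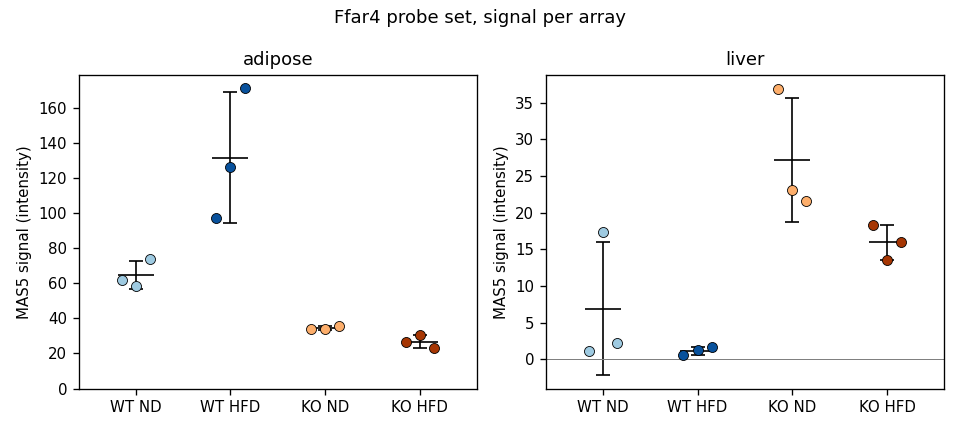
Ffar4 signal (intensity, vertical axis) on each array of the 4 groups (horizontal axis), in adipose tissue and in liver, with points for arrays and bars for mean ± SD. Adipose KO arrays on HFD lie at 23.1 to 30.5, below each WT array on HFD, while the highest liver signal, on a KO array on ND, is 36.8.

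On HFD, adipose tissue of KO mice held more macrophage transcripts and fewer endothelial transcripts than that of WT mice. Of 33 macrophage genes kept by the filter, 27 rose and 1 fell (29 and 1 adjusted over the list alone), with a median log2 difference of 1.62. Adgre1, which encodes the macrophage surface protein F4/80, rose by 2.24 ± 0.28 (4.73-fold, adjusted p = 0.000751). Ms4a7 rose by 2.19 ± 0.21, Clec7a, a receptor for fungal glucans, by 2.13 ± 0.25, and Cybb, a subunit of the phagocyte NADPH oxidase, by 2.05 ± 0.27. All 17 endothelial genes fell (17 over the list alone), with a median of -1.22. They included Kdr, a receptor for vascular endothelial growth factor, at -1.88 ± 0.23 (adjusted p = 0.000657), Eng at -1.68 ± 0.23 and the angiopoietin receptor gene Tek at -0.88 ± 0.12. The macrophage list passed camera at adjusted p = 3.99e-15 and the endothelial list at 9.69e-12, and each had adjusted p = 0.205 with an estimated correlation. The Actb 3'/5' ratio, a sign of RNA quality or labelling, also differed between these groups, at log2 0.73 ± 0.10 (SD) on KO and 1.44 ± 0.28 on WT arrays. The KO array of mouse 427 held the epithelial transcripts Krt19 (406) and Cdh1 (343), against at most 47.5 and 37.4 on the other HFD arrays, and the WT array of mouse 547 held the skeletal muscle transcripts Myh4 (918) and Mb (950).

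Genes of lipid-associated macrophages, inflammation, matrix and cell division moved the same way as the macrophage genes. Among 20 lipid-associated macrophage genes 14 rose and 0 fell (15 and 0 over the list alone, median 1.53), led by the protease gene Ctsk (2.83 ± 0.34) and the cholesterol ester hydrolase gene Nceh1 (2.39 ± 0.34). Of 22 inflammatory genes 13 rose (14 over the list alone, median 1.02), among them the monocyte chemokine gene Ccl2 (2.43 ± 0.45, adjusted p = 0.00358), Ccl8 (1.33) and Tlr2 (1.30). Of 35 extracellular matrix genes 18 rose and 1 fell (21 and 1 over the list alone, median 0.62), with the protease inhibitor gene Timp1 12.1-fold higher, Lum at 2.06 ± 0.24 and Col1a1 at 1.73 ± 0.24. Cell cycle genes rose in 11 of 20 (14 over the list alone, median 1.30), including Ccna2 (1.69), the replication factor genes Mcm5 (1.39) and Pcna (1.09). Immediate early genes rose in 12 of 21 and fell in 1 (14 and 1 over the list alone, median 0.71), with Egr2 at 3.29 ± 0.27 and Atf3 at 2.97 ± 0.39. Cholesterol synthesis genes rose in 14 of 20 (14 rose and 1 fell over the list alone, median 0.90), with Dhcr7 at 2.15, Fdps at 1.68 and Lss at 1.18. These lists passed camera at adjusted p = 9.9e-10, 3.67e-07, 1.87e-07, 1.92e-08, 2.77e-06 and 2.77e-06 in that order, and each had adjusted p = 0.205 with an estimated correlation.

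Lists of adipocyte, insulin signalling, fatty acid oxidation and oxidative phosphorylation genes shifted lower in KO mice on HFD, while most of their genes did not pass singly. Of 25 adipocyte genes 9 fell and 1 rose (10 and 1 over the list alone, median -0.63). Retn, which encodes the adipokine resistin, fell by 2.34 ± 0.40, the adiponectin receptor gene Adipor2 by 1.21, and Pparg, the main transcription factor of adipocyte differentiation, by 1.12 ± 0.19 (adjusted p = 0.00261). Values that did not pass were -0.36 for Adipoq (adjusted p = 0.224), -0.13 for Fabp4 (0.644, log2 0.0212 after quantile normalization), 0.95 for Lep (0.506) and -0.63 for the glucose transporter gene Slc2a4 (0.21). Insulin signalling genes fell in 10 of 23 and rose in 1 (10 and 2 over the list alone, median -0.50), with Gys1, glycogen synthase, at -1.64 and Pdpk1 at -0.61, while Grb14, an inhibitor of the insulin receptor, rose by 0.96. Fatty acid oxidation genes fell in 7 of 26 (10 over the list alone, median -0.42), including Vnn1 (-2.51), Acadvl (-0.84) and the carnitine carrier gene Slc25a20 (-0.76). Oxidative phosphorylation genes fell in 8 of 32 (8 over the list alone, median -0.21), with Ndufv1 at -0.61 and Ndufb8 at -0.58. These 4 lists had camera adjusted p = 0.00139, 0.0135, 0.00176 and 0.000864, and adjusted p = 0.499, 0.437, 0.437 and 0.544 with an estimated correlation. Skeletal muscle genes (0 rose and 1 fell of 10, camera adjusted p = 0.211) and epididymis and testis genes (1 rose of 17, camera adjusted p = 0.5) did not pass as lists. Hepatocyte genes had a median of 1.12 with 0 that rose and 1 that fell of 19 (0 and 1 over the list alone, camera adjusted p = 0.0539, 0.63 with an estimated correlation). Without mice 427 and 547 6 rose and 1 fell, with a median of 1.67 and camera adjusted p = 0.00391.

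**Figure D2:**
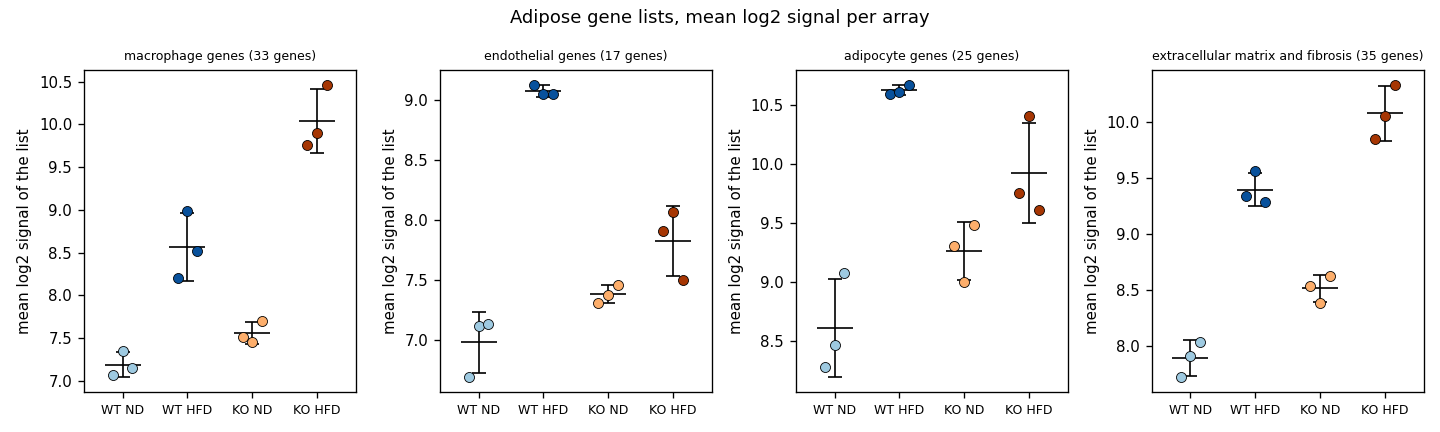
Mean log2 signal of 33 macrophage, 17 endothelial, 25 adipocyte and 35 extracellular matrix genes (vertical axis) on each adipose array of the 4 groups (horizontal axis), with points for arrays and bars for mean ± SD. Macrophage means lie at 9.76 to 10.46 on KO and 8.20 to 8.98 on WT arrays on HFD, and the endothelial means of WT arrays on HFD lie above those of each other group.

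Across all 11613 adipose genes tested, 1286 were higher and 1326 lower in KO mice on HFD, 1097 of them by at least 2-fold. The groups did not overlap for 38.0% of genes, against 10% by chance. The largest rise measured above the filter in both groups was in Pik3ap1, an adaptor of phosphoinositide 3-kinase signalling, at 4.55 ± 0.20 (23.4-fold, adjusted p = 1.6e-06, signals 706 and 30.2). Zranb3 rose by 3.75, Cd72, a B cell and myeloid receptor gene, by 3.69 ± 0.36, and Atp6v0d2, a subunit of the lysosomal proton pump, by 3.65. Gpr50 was at least 22.4-fold higher (signals 432 and 11.8, adjusted p = 0.000657), Dusp5 at least 5.62-fold (108 and 8.92, 0.00691), Fat3 at least 3.55-fold (68.5 and 5.01, 0.00261) and B4galnt1 at least 1.75-fold (33.8 and 2.60, 0.008). The largest falls were in Ces1f, a carboxylesterase gene, at -3.64 ± 0.36 (adjusted p = 0.000243), Fam13a at -3.36, the retinol-binding protein gene Rbp7 at -3.16 ± 0.30 and Rflna at -3.00. Acsm3 was at least 2.78-fold lower (2.78 and 53.6, adjusted p = 0.00231), Mycl at least 4.56-fold (7.57 and 88.1, 0.00182), Tmem88b at least 4.37-fold (from 84.3, 0.00248) and Nxpe2 at least 1.13-fold (2.44 and 21.8, 0.0134). Without KO mouse 429 the call of Nxpe2 was lost (adjusted p = 0.0561, over its alternatives 0.00016 to 0.0569) and 1569 genes were called, and without WT mouse 560 1642 genes were called. Of 31 lists tested 17 passed camera, 16 of them also passed fry, and 0 passed with an estimated correlation.

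On ND, few adipose genes differed between the genotypes. Npy, which encodes neuropeptide Y, was at least 36.5-fold lower in KO mice (signals 4.40 and 705, adjusted p = 0.00263), Tmem87a was lower by log2 -2.29 ± 0.22 (adjusted p = 0.00263), and Pik3ap1 was higher by 1.95 ± 0.20 (adjusted p = 0.00409, signals 82.9 and 21.4). Cd209g, a C-type lectin gene, was at least 3.17-fold higher (61.2 and 5.14, adjusted p = 0.0125). In all, 25 of 11613 genes were higher and 4 lower, with 1617 at an unadjusted p under 0.05 and the groups apart for 23.2% of genes, against 10% by chance. Of 35 matrix genes 1 rose over all genes, Sparc (1.04 ± 0.16, adjusted p = 0.0238), and 24 rose adjusted over the list alone (median 0.81, camera adjusted p = 2e-13, adjusted p = 0.451 with an estimated correlation). Of 25 adipocyte genes 0 changed over all genes and 8 rose over the list alone (median 0.53, camera adjusted p = 0.000921, 0.629 with an estimated correlation), and of 17 endothelial genes 0 and 4 (median 0.39, 0.000372, 0.629). Epididymis and testis genes had a median of -0.08, a mean of -0.94 and a camera adjusted p of 0.0439 toward lower levels (0.629 with an estimated correlation), a call lost without mouse 686 (0.128), 690 (0.11), 719 (0.0558) or 720 (0.0893). The sperm transcripts Prm1 and Tnp1 set the WT arrays of mice 686 (4371 and 4411) and 690 (4617 and 2827) apart from that of mouse 687, where Prm1 was 451, and from KO arrays, where Prm1 was 205 to 366.

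The count on ND depended on single arrays: it was 408 without WT mouse 687, 11 without WT mouse 686, and 7, 18 and 9 without KO mice 718, 719 and 720. The calls of Npy and Tmem87a survived each of these, while that of Cd209g was lost without KO mouse 718 (adjusted p = 0.0736), KO mouse 720 (0.067), WT mouse 686 (0.0673) or both 686 and 690 (0.0663), over a range of 0.00407 to 0.0736. Without both 686 and 690, which held sperm transcripts, 1 WT ND array was left, and Pik3ap1 also lost its call (adjusted p = 0.0639, over its alternatives 0.00115 to 0.0639) with its log2 difference at 1.93 against 1.95. Calls lost more widely were those of Zfp52 (2.40, adjusted p = 0.0474, over its alternatives 0.0252 to 0.263), Fcor (2.13, 0.0238, 0.0105 to 0.113), Ift140 (-1.02, 0.0387, 0.00345 to 0.343) and Vamp7 (-0.94, 0.0434, 0.0194 to 0.263). Without mice 718, 719, 720, 686 and 690 the adjusted p of Zfp52 was 0.202, 0.0856, 0.263, 0.0617 and 0.0864, that of Ift140 0.144, 0.0972, 0.238, 0.12 and 0.0852, and that of Vamp7 0.202, 0.0846, 0.263, 0.0699 and 0.0745. For Fcor it was 0.0733, 0.0575, 0.113 and 0.0786 without mice 718, 719, 720 and 686. With only the arrays of the 2 groups Zfp52, Fcor, Ift140 and Vamp7 had 0.0785, 0.0749, 0.11 and 0.0804. They also lost their calls without both 686 and 690, but with 1 WT ND array left this does not show that they rested on sperm transcripts. With no filter Zfp52, Ift140 and Vamp7 had 0.0664, 0.0542 and 0.0542. Sparc lost its call without mouse 718 (0.0987), 720 (0.0855), 686 (0.0775) or both 686 and 690 (0.111), with no filter (0.0533), with only the arrays of the 2 groups (0.0828) and with the mean of its probe sets (0.229).

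In WT mice, the deepest falls on HFD in fat were in transcripts of the epididymis, the organ that the fat pad adjoins. All 17 kept genes of the epididymis and testis list fell (17 over the list alone, camera adjusted p = 1.25e-09, 0.125 with an estimated correlation). Lcn5, an epididymal lipocalin gene, was at least 443-fold lower (signals 1.71 and 8559), Adam7 at least 306-fold (1.34 and 5903) and Rnase10 at least 298-fold (8.02 and 5749). Fitted values of these genes depend on the floor, and their median fitted log2 difference of -9.19 became a median of at least 82.8-fold (12.6 to 443) over the 13 genes with a bound. Lcn9 and Cst11 were at least 306- and 207-fold lower. Outside the list, Lypd8, Defb15, Serpina1f and Spink8 were at least 223-, 230.2-, 242- and 345-fold lower. Lcn5 signals were 6230 to 10683 on every ND array of either genotype and 1.08 to 7.83 on every HFD array. The epithelial transcripts Krt19 (477 to 666) and Cdh1 (885 to 1163) were also high on each ND array. In each adipose diet comparison, fat with these transcripts was thus set against fat with few of them.

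**Figure D3:**
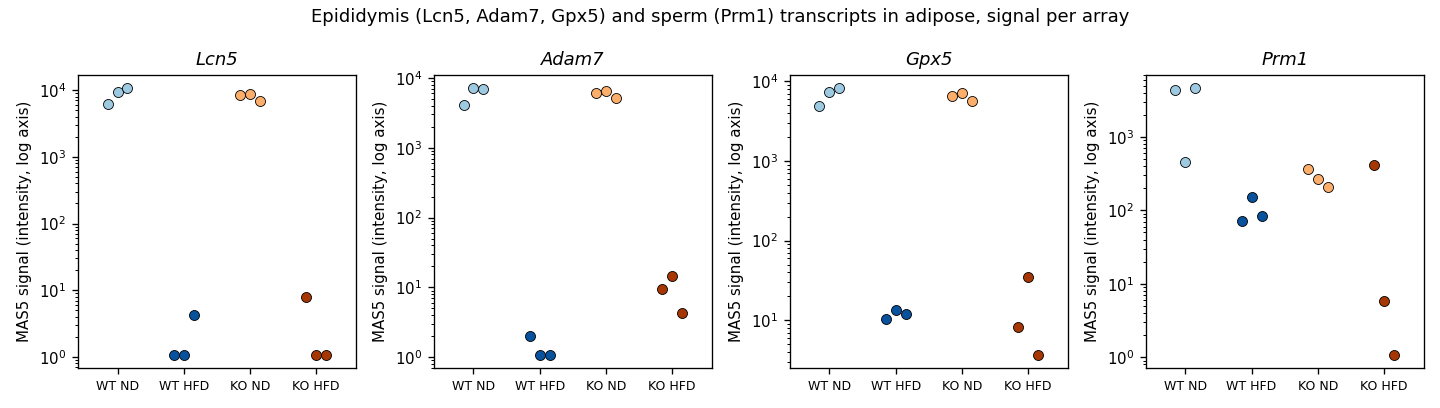
Signal (intensity, logarithmic vertical axis) of Lcn5, Adam7, Gpx5 and Prm1 on each adipose array of the 4 groups (horizontal axis), with values under the floor drawn at the floor of 1.08. Gpx5 lies at 4935 to 8196 on ND arrays and 3.68 to 34.6 on HFD arrays, and Prm1 stands at 4371 and 4617 on the WT ND arrays of mice 686 and 690.

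Adipocyte, vascular, matrix and immune genes rose in WT fat on HFD. Since ND fat of both genotypes held epididymis transcripts, other tissue on ND was not separated from diet effects in fat, here or in KO mice. Of 25 adipocyte genes 21 rose (21 over the list alone, median 1.61), including Pparg (2.50 ± 0.19), Cebpa (2.49), the glycerol channel gene Aqp7 (3.44) and Lep, which encodes leptin (5.90 ± 0.94, adjusted p = 0.000331, signals 1687 and 28.2). Sfrp5 was at least 58.0-fold higher (1120 and 17.8, adjusted p = 1.92e-05). All 17 endothelial genes rose (17 over the list alone, median 2.18), with Cdh5, vascular cadherin, at 2.91, Kdr at 2.41 and Tek at 2.20 ± 0.12. Of 35 matrix genes 27 rose (27 over the list alone, median 1.73), with Col4a2 at 2.32 and Sparc at 2.19, and of 33 macrophage genes 27 rose and 1 fell (28 and 1 over the list alone, median 1.68), with Csf1r, the receptor of the macrophage growth factor, at 1.86 and Mrc1 at 1.68, while Cd52 fell by 3.96. Camera adjusted p values were 1.75e-07, 1.25e-09, 1.25e-09 and 5.06e-08, against adjusted p = 0.411, 0.386, 0.386 and 0.434 with an estimated correlation. Receptors for fatty acids and metabolites rose in 6 of 9 (6 over the list alone, median 2.53, camera adjusted p = 0.00613, 0.411 with an estimated correlation), with the succinate receptor gene Sucnr1 at 3.36, the short-chain fatty acid receptor gene Ffar2 at 2.53 and the lactate receptor gene Hcar1 at least 4.40-fold higher. Cholesterol synthesis genes fell in 11 of 20 and rose in 3 (11 and 3 over the list alone, median -0.66, camera adjusted p = 0.011, 0.411 with an estimated correlation), with Tm7sf2 at -3.16, Fdps at -2.68 and Nsdhl at -1.51. The 17 fatty acid oxidation genes that rose, of 26 with 4 falling (18 and 4 over the list alone, median 1.04, camera adjusted p = 0.00202, 0.503 with an estimated correlation), included Decr1 (1.79) and Slc25a20 (1.46). Hepatocyte genes fell in 15 of 19 and rose in 1 (15 and 1 over the list alone, median -2.20, camera adjusted p = 0.011, 0.67 with an estimated correlation).

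Of 11613 genes 3239 were higher and 3184 lower on HFD in WT fat, 3333 by at least 2-fold, and the groups did not overlap for 61.2% of genes, against 10% by chance. Other large rises were in Aplnr, the apelin receptor gene (4.66 ± 0.21, adjusted p = 1.15e-07), the interferon-induced chemokine gene Cxcl9 (4.35), Cd209g (at least 6.34-fold, 122 and 5.14), Prr32 (adjusted p = 0.000623, 193 and 6.05), Dusp9 (at least 6.58-fold, 127 and 5.56) and Ankef1 (at least 19.4-fold, 375 and 16.5). Another probe set of Ankef1 ran the opposite way, and its call was lost with the mean of its probe sets (adjusted p = 0.336, over its alternatives 2.05e-05 to 0.336). After quantile normalization the median log2 difference of all genes moved from -0.03 to 0.10.

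In KO mice, HFD raised macrophage, matrix and inflammatory genes in fat, while endothelial genes rose less than in WT mice. Of 33 macrophage genes 29 rose and 1 fell (30 and 1 over the list alone, median 2.83), with Adgre1 at 3.74 ± 0.28 and Cybb at 3.70. Of 20 lipid-associated macrophage genes 18 rose and 1 fell (18 and 1 over the list alone, median 2.25), with Trem2, a lipid-sensing receptor of these cells, at 5.73 ± 0.73 (adjusted p = 0.000108), Gpnmb at 4.24 and Ctsk at 4.10. Of 35 matrix genes 31 rose and 1 fell (31 and 2 over the list alone, median 1.76), led by Col6a1 (1.82) and Col5a2 (2.81), and of 22 inflammatory genes 18 rose and 1 fell (20 and 1 over the list alone, median 1.46), with Ccl2 at 4.43. Cell cycle genes rose in 13 of 20 (13 over the list alone, median 1.57), with Mcm5 at 2.20. These lists had camera adjusted p = 6.19e-16, 1.12e-08, 2.59e-13, 8.44e-08 and 1.56e-05, against adjusted p = 0.308, 0.308, 0.162, 0.162 and 0.435 with an estimated correlation. Endothelial genes rose in 8 of 17 (8 over the list alone, median 0.49, camera adjusted p = 0.0267, 0.683 with an estimated correlation), with Cdh5 at 0.98 and Tek at 0.74, and their list call was lost without KO mouse 427 (adjusted p = 0.0613) or 428 (0.0951). Epididymis and testis genes fell in 14 of 17 (15 over the list alone, camera adjusted p = 2.27e-09, 0.153 with an estimated correlation), with Lcn5 at least 411-fold lower and a median of at least 99.9-fold (1.90 to 411) over the 17 genes.

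In KO fat 2564 genes were higher and 3090 lower on HFD, 2760 by at least 2-fold, and the groups were apart for 62.2% of genes, against 10% by chance. The largest rises were in Ubd, a ubiquitin-like gene induced by interferon (6.29 ± 0.45, adjusted p = 3.37e-06), Rgs1 (5.82), Trem2 and Gpr50 (at least 22.4-fold, 432 and 7.23), and the largest falls in Lcn5, Lcn9, Cst11 and Crisp4 (at least 411-, 299.6-, 202- and 78.4-fold). The diet effects of the genotypes correlated with r = 0.83 across genes, which are not independent replicates. Epididymis transcripts on the ND arrays of both genotypes may have raised this value and the overlaps that follow. In both genotypes 1839 genes rose, against 715 for independent lists, 2099 fell, against 847, and 120 changed in opposite directions.

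The diet effect on fat differed between the genotypes for endothelial, adipocyte, macrophage and cell cycle genes. Of 17 endothelial genes 15 had a negative interaction (17 over the list alone), with a median of -1.69, among them Kdr (-2.60 ± 0.33, adjusted p = 0.0033), Egfl7 (-1.69), Tek (-1.46 ± 0.17, adjusted p = 0.00283) and Esam (-1.43). Adipocyte genes were negative in 10 of 25 (13 over the list alone, median -1.29), with Pparg at -1.78 ± 0.27 (adjusted p = 0.00511). Macrophage genes were positive in 10 of 33 (22 positive and 1 negative over the list alone, median 1.31), with Ms4a7 at 1.82 (adjusted p = 0.00544, 0.074 with the mean of its probe sets), and lipid-associated macrophage genes in 9 of 20 (9 and 1 over the list alone, median 1.37), with Atp6v0d2 at 3.77 and Nceh1 at 2.66. Cell cycle genes were positive in 10 of 20 (16 over the list alone, median 1.83). Camera adjusted p values were 5.73e-13, 5.58e-06, 5e-09, 5.85e-07 and 9.3e-10, against adjusted p = 0.349 for the endothelial and 0.371 for each other list with an estimated correlation. Matrix genes were positive in 3 and negative in 1 of 35 and did not pass as a list (median -0.03, mean 0.05, camera adjusted p = 0.604). Over all genes 437 interactions were positive and 836 negative. Fitted interactions of Npy (7.95) and Gpr50 (5.58) depend on the floor. The count of 1273 fell to 767, 784 and 722 without HFD mice 429, 546 and 560, to 639, 699 and 680 without KO ND mice 718, 719 and 720, and to 382 without both WT ND mice that held sperm transcripts, 686 and 690. That last fit kept 1 WT ND array, taken to vary like the arrays of the other groups, so its count does not show that the interaction rested on sperm transcripts. The Actb 3'/5' log2 ratio went from 0.90 ± 0.02 (SD) on ND to 1.44 ± 0.28 on HFD in WT fat and from 0.80 ± 0.07 to 0.73 ± 0.10 in KO fat, so RNA quality or labelling was not separated from this interaction.

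Averaged over the diets, KO fat held more Pik3ap1 (3.25 ± 0.14, adjusted p = 1.42e-06) and more transcripts of macrophages and matrix, and less Ces1f (-1.89 ± 0.25). Macrophage genes rose in 26 of 33 (27 over the list alone, median 0.99), including Ptprc (1.32) and Itgax, the integrin CD11c, whose fitted value (2.13) depends on the floor. Matrix genes rose in 24 of 35 (29 rose and 1 fell over the list alone, median 0.67), with Col1a1 at 1.44 ± 0.17, Lum at 1.31 and Col6a1 at 0.88. Endothelial genes fell in 3 of 17 (11 over the list alone, median -0.41). In that order camera gave adjusted p = 1.42e-16, 1.67e-14 and 4.57e-07, against adjusted p = 0.318, 0.167 and 0.323 with an estimated correlation. For Ces1f, macrophage and endothelial genes the average does not stand for a like effect on each diet. Ces1f fell further on HFD, the macrophage list had a positive interaction, and the endothelial median was negative on HFD and positive on ND. The HFD arrays in these averages also differed by genotype in the Actb 3'/5' ratio, so RNA quality or labelling was not separated from them. Of 11613 genes 859 were higher and 395 lower. This count of 1254 was 807, 712, 805, 745, 726 and 663 without mice 429, 560, 690, 718, 719 and 720, and 354 without both 686 and 690, again with 1 WT ND array left. The genotype effects on HFD and on ND did not run together across adipose genes (r = 0.006), with 5 genes higher on both diets against 2.77 for independent lists and 0 lower on both against 0.457. A further 3 genes were called in opposite directions.

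In liver on HFD, KO mice held more transcripts of lipid uptake, lipid droplets and lipogenesis than WT mice. Cd36, a fatty acid translocase, rose by 2.36 ± 0.15 (5.14-fold, adjusted p = 1.19e-06), with signals of 831 to 1030 on KO and 145 to 218 on WT arrays of either diet. Mogat1, an enzyme of triglyceride synthesis, rose by 3.77 ± 0.35, the droplet protein genes Plin4 and Cidec by 3.01 and 2.42, and Vldlr by 2.64. Cidea, another droplet protein, was at least 83.6-fold higher (signals 1082 and 4.01, adjusted p = 0.000211). Of 24 genes of lipid droplets and lipid uptake 9 rose (10 rose and 1 fell over the list alone, median 0.21, mean 1.18), and of 24 lipogenesis genes 7 rose (11 rose and 1 fell over the list alone, median 0.35), with the desaturase gene Scd1 at 3.47 ± 0.37 and malic enzyme Me1 at 3.03 ± 0.26. The lists had camera adjusted p = 1.17e-06 and 4.51e-06, and each had adjusted p = 0.0695 with an estimated correlation.

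**Figure D4:**
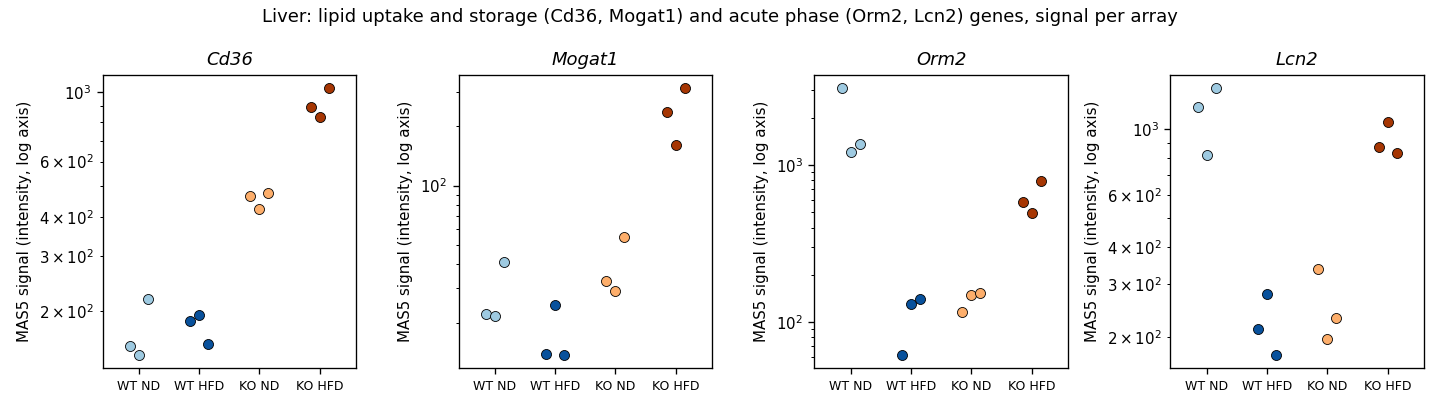
Signal (intensity, logarithmic vertical axis) of Cd36, Mogat1, Orm2 and Lcn2 on each liver array of the 4 groups (horizontal axis), with points for arrays. Cd36 lies at 831 to 1030 on KO HFD and 422 to 476 on KO ND arrays, above 145 to 218 on WT arrays, and Orm2 is high in WT ND (1217 to 3091) and KO HFD (491 to 789.9) mice.

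Macrophage, matrix and immediate early genes were also higher in KO liver on HFD. Of 32 macrophage genes 9 rose and 1 fell (16 and 1 over the list alone, median 0.66), with Cd52 at 1.38 and the lysosomal protease gene Ctss at 0.55. Of 17 lipid-associated macrophage genes 7 rose (8 over the list alone, median 0.32), with Lgals1, galectin-1, at 4.26 ± 0.24 (19.2-fold, adjusted p = 2.51e-07), Anxa5 at 1.81 and Capg at 1.77. Of 28 matrix genes 7 rose and 1 fell (11 and 1 over the list alone, median 0.59), with the collagen genes Col3a1 at 2.51 ± 0.28 and Col1a2 at 2.15. Of 18 immediate early genes 7 rose (11 over the list alone, median 1.23), with Atf3 at 3.35, Dusp1 at 2.27 and Klf6 at 1.67. Camera adjusted p values were 7.7e-09, 1.02e-05, 3.03e-07 and 2.14e-08, against adjusted p = 0.149, 0.0695, 0.0695 and 0.146 with an estimated correlation. Male-biased liver genes fell in 6 of 14 (7 fell and 1 rose over the list alone, median -0.79, camera adjusted p = 4.51e-06, 0.088 with an estimated correlation), including Slco1a1 (-1.42) and the complement gene C6 (-0.90). Acute phase genes rose in 6 of 24 and fell in 2 (6 and 3 over the list alone) and did not pass as a list (median 0.02, camera adjusted p = 0.384), while Orm2 rose by 2.55 ± 0.35 and Lcn2 by 2.07 ± 0.23. Hepatocyte genes fell in 7 of 20 and rose in 1 (13 and 1 over the list alone, median -0.30, camera adjusted p = 1.59e-05, 0.339 with an estimated correlation), a list call lost after quantile normalization (adjusted p = 0.548). The Actb 3'/5' ratio on these arrays was log2 1.70 ± 0.01 (SD) in KO and 2.04 ± 0.05 in WT mice. The KO arrays (1.69 to 1.71) and WT arrays (1.99 to 2.09) did not overlap. RNA quality or labelling was thus not separated from the genotype effect in liver on HFD, including that on the lipid genes above.

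In liver on HFD, 2 cytochrome P450 genes of the Cyp2c family, whose members are close paralogs, changed in opposite directions. Cyp2c39 was at least 150.1-fold higher in KO mice (signals 1943 and 8.20, adjusted p = 1.74e-07), and Cyp2c37 was lower by log2 -5.74 ± 0.21 (adjusted p = 6.26e-09, signals 67.1 and 3576). Whether strain differences near Ffar4 or under the probes gave these changes was not tested for the 2 genes on either diet. Moxd1 was at least 65.9-fold lower (1.10 and 854, adjusted p = 8.62e-06). Cyp2b9, a female-biased P450 gene of mouse liver, rose by 5.37 ± 0.48, Ly6d by 4.92, the thyroxine-binding globulin gene Serpina7 by 3.65, and Themis was at least 11.2-fold higher (145 and 7.09, adjusted p = 0.00861). H2-Bl fell by 2.86, Hsd3b5, a male-biased steroid enzyme gene, by 2.42, and Enho by 3.10, although another probe set of Enho ran the opposite way. Tcea2 was at least 2.92-fold lower (adjusted p = 0.000774, 6.29e-05 to 0.187 over its alternatives, the highest with the mean of its probe sets). Of 11125 genes 415 were higher and 332 lower, 257 by at least 2-fold, and the groups were apart for 29.3% of genes, against 10% by chance. The count of 747 was 274, 423, 385 and 404 without mice 427, 429, 546 and 547. The calls of Myom1 (at least 1.46-fold lower, adjusted p = 0.0321, 0.00753 to 0.117 over its alternatives) and Ovgp1 (at least 1.72-fold lower, 0.0433, 0.00652 to 0.108) were not stable. Myom1 lost its call without mouse 427 (0.117) or 428 (0.0888), with quantile normalization (0.0546) and with no filter (0.0602). Ovgp1 lost it without 427 (0.105), 429 (0.0794), 546 (0.108), 547 (0.106) or 560 (0.0803), with quantile normalization (0.0512), with no filter (0.0777) and with no floor (0.0515). Of 30 lists 16 passed camera, 11 of them also fry, and 0 passed with an estimated correlation.

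On ND, KO liver held fewer acute phase transcripts than WT liver. Of 24 genes 9 fell (13 over the list alone, median -0.54, camera adjusted p = 2.61e-10, 0.626 with an estimated correlation), with Orm2, an orosomucoid gene, at -3.65 ± 0.35 (adjusted p = 0.000113), Lcn2, lipocalin-2, at -2.15 ± 0.23 and Serpina3n at -1.03. Cd36 rose by 1.42 ± 0.15, Fitm1, a droplet-forming protein gene, by 1.95, Me1 by 1.43, Lgals1 by 2.07 and the multidrug transporter gene Abcc3 by 1.21. Other lipid genes fell: Acacb by 1.36 (adjusted p = 0.00481, 0.00305 to 0.628 over its alternatives) and the lipase gene Pnpla2 by 0.95 (0.00708, 0.0055 to 0.226), both lost with the mean of their probe sets, and Plin3 by 0.79 (0.0195, 0.0173 to 0.0811). The call of Plin3 was lost without mouse 687 (0.0811), 718 (0.0792) or 720 (0.0608). Lipid droplet genes rose in 3 of 24 and fell in 1 (3 and 2 over the list alone, camera adjusted p = 0.0821, 0.732 with an estimated correlation), and lipogenesis genes rose in 2 of 24 and fell in 1 (3 and 1 over the list alone, 0.0579, 0.732), so neither passed as a list. Hepatocyte genes fell in 3 of 20 (6 over the list alone, median -0.22, camera adjusted p = 4.96e-05, 0.732 with an estimated correlation), a list call lost after quantile normalization (adjusted p = 0.305). Cyp2c39 rose by 5.50 ± 0.42 (adjusted p = 2.12e-05, signals 2161 and 47.7), the carboxylesterase gene Ces1g by 3.56 ± 0.28, Cyp2c37 fell by 5.92 ± 0.21 and Scara5 by 4.55, and Moxd1 was at least 87.5-fold lower (1.94 and 1133). Cxcl14 was at least 6.45-fold lower (2.69 and 83.5, adjusted p = 0.00133, 0.000171 to 0.429 over its alternatives, the highest with only the arrays of the groups compared). On those arrays the brightest probe set of Cxcl14 was another one, at log2 -0.64. Clec2h was at least 1.76-fold higher (22.8 and 2.33, adjusted p = 0.00837, 0.00334 to 0.0592 over its alternatives, the highest with the mean of its probe sets), its weakest probe set being at 0.38, and Kbtbd11 at least 2.08-fold (27.0 and 2.71, 0.0199), a call lost without WT mouse 690 (0.055) or KO mice 719 (0.0565) and 720 (0.0878), over a range of 0.014 to 0.0878. Of 11125 genes 247 were higher and 277 lower, 176 by at least 2-fold, and the groups were apart for 25.6% of genes, against 10% by chance. The count of 524 was 199, 194, 321 and 198 without mice 687, 718, 719 and 720. The genotype effects on HFD and ND correlated with r = 0.32 across liver genes, with 74 genes higher on both diets against 9.21 for independent lists, 43 lower on both against 8.27, and 8 opposite.

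In WT liver, HFD lowered acute phase genes and raised interferon-induced genes. Acute phase genes fell in 8 of 24 and rose in 1 (9 and 1 over the list alone, median -0.29), with Orm2 at -4.05 ± 0.35 (adjusted p = 5.84e-05), the serum amyloid gene Saa2 at -3.83 and Lcn2 at -2.34. Interferon-induced genes rose in 7 of 22 (11 over the list alone, median 0.64), with Ifit1 at 1.47. Unfolded protein and stress response genes rose in 6 of 25 (13 rose and 1 fell over the list alone, median 0.69). Camera adjusted p values were 1.08e-05, 6.88e-05 and 0.00112, and each had adjusted p = 0.651 with an estimated correlation. Clock genes rose in 5 of 18 and fell in 1 (8 and 2 over the list alone) without passing as a list (camera adjusted p = 0.115), and Dbp, a clock output gene, rose by 3.25 ± 0.50, its signal being 97.4 to 619.7 on ND and 1489 to 2527 on HFD arrays of either genotype. Other large rises were in Hsd3b5 (4.66 ± 0.43, adjusted p = 8.71e-05), Cxcl1 (3.74, at 1.49 in its weakest probe set), B3galt1 (3.09, at 0.83 in its weakest), Dct (at least 23.1-fold, 299 and 10.2) and Clec2h (at least 2.60-fold, 33.7 and 2.33), and other large falls in the cell cycle inhibitor gene Cdkn1a (-4.76), the stress gene Ddit4 (-4.46), Cyp2b10 (-4.35), Cyp39a1 (-3.56), Rasd1 (at least 3.17-fold, 2.33 and 41.1) and Mmd2 (at least 5.14-fold, 6.42 and 66.6). The rises of Serpina4-ps1 (3.68, adjusted p = 0.015, 0.00026 to 0.0958 over its alternatives) and Kbtbd11 (at least 1.80-fold, 0.0136, 0.00436 to 0.0607) were lost, the former without mouse 546 (0.0958), 547 (0.0958) or 690 (0.0518) or with only the arrays of the 2 groups (0.0655). The latter was lost without mouse 547 (0.0607). Of 11125 genes 720 were higher and 672 lower, 365 by at least 2-fold, the groups being apart for 28.9% of genes against 10% by chance. The count of 1392 was 745, 672 and 841 without mice 546, 547 and 687. The Gapdh 3'/5' ratio moved with diet in both tissues, at log2 -0.48 to -0.27 on ND and -0.11 to 0.21 on HFD arrays. The Actb ratio moved too, from log2 1.18 ± 0.07 (SD) on ND to 2.04 ± 0.05 on HFD in WT liver and from 1.29 ± 0.05 to 1.70 ± 0.01 in KO liver, so diet and RNA quality or labelling were not separated.

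In KO liver, HFD raised macrophage, interferon-induced and matrix genes and lowered genes of fatty acid oxidation. Of 32 macrophage genes 24 rose and 1 fell (26 and 1 over the list alone, median 1.05), with Lyz2, lysozyme, at 1.34, Ctss at 1.13 and Csf1r at 1.02. Of 22 interferon-induced genes 15 rose (17 over the list alone, median 1.20), with Ifi27l2a at 2.70, Xaf1 at 2.53 and the viral RNA sensor gene Ifih1 at 1.39. Of 28 matrix genes 13 rose (14 over the list alone, median 0.59), with Col3a1 at 2.68, and of 26 fatty acid oxidation genes 10 fell (10 over the list alone, median -0.28), with Acot1 at -1.67 and Ehhadh at -1.47. By camera their adjusted p was 1.04e-13, 9.56e-12, 0.000117 and 5.35e-05, against adjusted p = 0.267, 0.267, 0.326 and 0.396 with an estimated correlation. Lipogenesis genes rose in 8 of 24 and fell in 1 (9 and 1 over the list alone, median 0.16, camera adjusted p = 0.0379, 0.396 with an estimated correlation), with Srebf1, the transcription factor of this pathway, at 2.52 ± 0.22 and Thrsp at 3.62, and the list call was lost without mouse 427 (0.0947) or 719 (0.0828). Gluconeogenesis and glucose handling genes fell in 6 of 17 and rose in 1 (8 and 1 over the list alone, median -0.39, camera adjusted p = 0.000728, 0.326 with an estimated correlation), with the tyrosine aminotransferase gene Tat at -1.69 and Pck1 at -1.07. The largest rises were in Cidea (at least 83.6-fold, 1082 and 5.66, adjusted p = 0.000234), Serpina7 (4.87), Cxcl1 (4.42) and the growth arrest gene Gadd45a (4.17), and the largest falls in Asic5 (-2.98 ± 0.22), Prdm11 (at least 5.55-fold, 4.35 and 71.8), Rnf25 (at least 7.59-fold, 11.5 and 98.3, at log2 -0.57 in its other probe set) and Tcea2 (at least 2.42-fold, adjusted p = 0.000754, 0.000187 to 0.0655 over its alternatives, the highest with the mean of its probe sets). Of 11125 genes 1019 were higher and 820 lower, 502 by at least 2-fold, the groups being apart for 38.6% of genes against 10% by chance. The count of 1839 was 1181, 1128, 1187 and 1138 without mice 427, 429, 718 and 720. The diet effects of WT and KO liver correlated with r = 0.42 across genes, with 280 genes higher in both against 65.9 for independent lists, 301 lower against 49.5, and 21 opposite.

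In liver the response of some acute phase genes to diet differed between the genotypes. Orm2 fell on HFD in WT mice (-4.05) and rose in KO mice (2.15), an interaction of 6.19 ± 0.49 (adjusted p = 5.58e-05), and Lcn2 fell (-2.34) and rose (1.88), an interaction of 4.22 ± 0.33 (adjusted p = 5.58e-05). Saa2 had an interaction of 5.98 (adjusted p = 0.012) and Orm3 of 3.09. Of 24 acute phase genes 5 had a positive interaction (10 over the list alone, median 0.34, camera adjusted p = 1.64e-08, 0.201 with an estimated correlation), and of 32 macrophage genes 2 (11 over the list alone, median 0.68, 4.56e-09, 0.218), among them Ctss at 0.96 ± 0.13. Lipid droplet genes were positive in 3 of 24 (7 over the list alone, median 0.25, camera adjusted p = 0.00146, 0.218 with an estimated correlation), with Mogat1 at 3.30, and the fitted interaction of Cidea (7.57) depends on the floor. Hsd3b5 (-4.06), Asic5 (-1.92) and Mlxipl, a glucose-sensing transcription factor gene (-1.47), had negative interactions. The Actb 3'/5' log2 ratio went from 1.18 ± 0.07 (SD) to 2.04 ± 0.05 with HFD in WT liver and from 1.29 ± 0.05 to 1.70 ± 0.01 in KO liver, so RNA quality or labelling was not separated from this interaction either. In all 69 of 11125 genes were positive and 41 negative. This count of 110 was 42, 35, 62, 49, 55, 42, 71 and 35 without mice 427, 429, 546, 547, 687, 718, 719 and 720.

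Averaged over the diets, KO liver held more Lgals1 (3.17), Me1 (2.23) and Cd36 (1.89 ± 0.11, adjusted p = 2.45e-07), and less Cyp2c37 (-5.83 ± 0.15, adjusted p = 5.46e-11) and H2-Bl (-3.51). Cyp2c39 (6.70 ± 0.30, adjusted p = 2.16e-08), Cyp2b9 (adjusted p = 1.42e-05), Themis (3.39), Cidea (4.29), Cxcl14 (-3.62) and Moxd1 (-9.40) also changed, with fitted values that depend on the floor. Lipogenesis genes rose in 6 of 24 (9 rose and 1 fell over the list alone, median 0.32), with Scd1 at 2.32, and lipid droplet genes in 8 of 24 (8 rose and 1 fell over the list alone, median 0.15), with Vldlr at 2.19 and Mogat1 at 2.12. Both lists had adjusted p = 0.161 with an estimated correlation, against camera adjusted p = 3.97e-05 and 4.11e-05. Of 11125 genes 606 were higher and 684 lower, and the count of 1290 was 755 and 853 without mice 427 and 546. The liver HFD arrays in these averages also differed by genotype in the Actb 3'/5' ratio.

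In both tissues 142 genes differed between the genotypes in the same direction averaged over the diets, 93 higher and 49 lower in KO mice, against 40.2 and 21.8 for independent lists, and 33 differed in opposite directions. Both tissues came from the same 12 mice, whose arrays deviated together (correlations of 0.0335 to 0.125), so shared mice may have raised the overlap over these values. The smallest p values were in Pik3ap1, which rose by 3.25 in fat and 3.34 in liver. Also changed in both were Efhd2 (1.94 and 1.40), Mcm5 (0.73 and 1.24), Col3a1 (0.78 and 1.64), Slc39a11 (0.73 and 0.56) and Slc43a1 (-0.94 and -1.34). So were Ubd (1.85 and 2.31) and Decr2, a peroxisomal dienoyl-CoA reductase gene (-1.34 and -1.20), whose fitted values depend on the floor in both tissues for Ubd and in fat for Decr2. Further such genes were Cyb5b (0.65 and 0.91), Tubb2a (0.62 and 1.32), Cdk6 (0.81 and 0.51), Ociad2 (0.92 and 0.54) and Zfp955b (-0.71 and -0.74). Taf15 (-1.27 and -0.95), Gosr1 (-0.63 in both), Vamp3 (1.02 and 1.09) and Nudt9 (0.45 and 0.85) lost the call in both tissues, and Kmt5a (0.49 and 0.84) and Stk38l (0.64 and 0.77) in liver, with the mean of their probe sets, where adjusted p reached 0.539 for Gosr1 in fat. In fat the calls of Ubd (adjusted p = 0.0633), Cdk6 (0.0734), Zfp955b (0.0734), Ociad2 (0.0541), Tubb2a (0.068), Stk38l (0.0825) and Cyb5b (0.0857) were lost without mice 686 and 690, when 1 WT ND array was left. Their log2 differences were then 1.68, 0.78, -0.64, 0.92, 0.51, 0.57 and 0.59, near those of all arrays. With the mean of probe sets the calls of Cyb5b (0.27, adjusted p = 0.171) and Tubb2a (0.40, 0.053) were also lost in fat. Over its alternatives in fat adjusted p was 0.00342 to 0.0633 for Ubd, 0.00608 to 0.0734 for Cdk6, 0.00611 to 0.0734 for Zfp955b, 0.00232 to 0.0541 for Ociad2, 0.00393 to 0.068 for Tubb2a, 0.00742 to 0.0825 for Stk38l and 0.00819 to 0.171 for Cyb5b. Ffar4 lies on chromosome 19 by the GRCm38.p6 gene table, and so did 11 of the 142 genes (7.75%), against 372 of the 10119 genes tested in both tissues (3.69%, 1-sided Fisher's exact test p = 0.0158, odds ratio 2.23). Among the 100 tested genes nearest to Ffar4, 50 on each side, 6 had changed in both tissues (Fisher's exact p = 0.00282). They were Cdc37l1, Ric1, Lipa, Fra10ac1, Pik3ap1 and Pyroxd2, which stand 45, 38 and 18 tested genes before and 2, 16 and 32 after it.

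**Figure D5:**
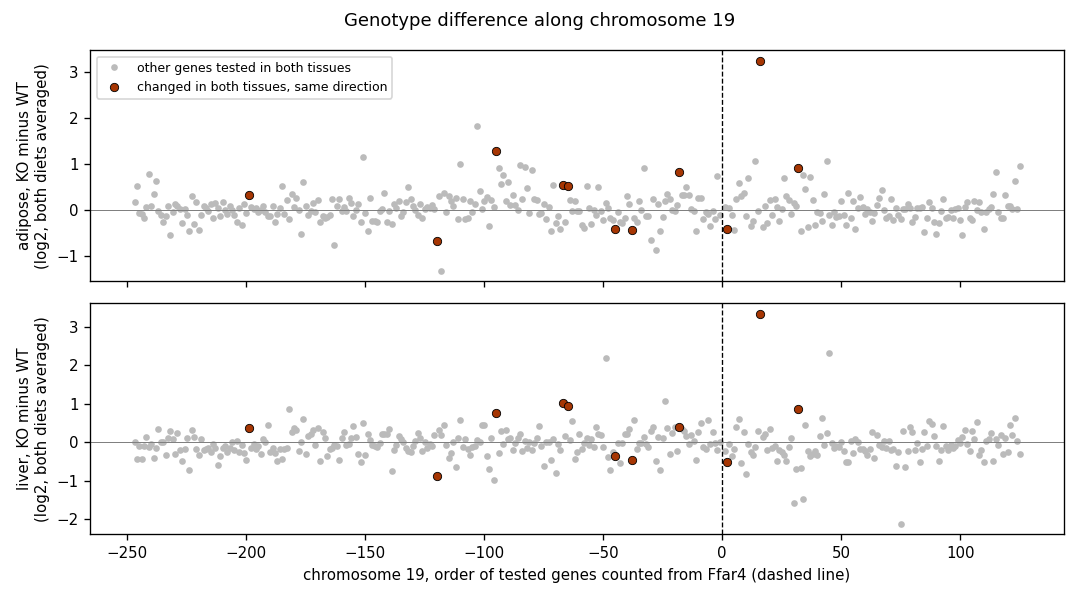
KO minus WT log2 difference averaged over diets (vertical axis) of chromosome 19 genes tested in both tissues, in the order of the GRCm38.p6 table counted from Ffar4 (horizontal axis), for adipose tissue and liver, with genes changed in both in the same direction marked. Pik3ap1, 16 tested genes after Ffar4, stands at 3.25 and 3.34.

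The genotype effect on HFD differed between the tissues for genes of lipid uptake and for endothelial genes, among others. Mogat1 had an adipose minus liver difference of -5.99 ± 0.50 (adjusted p = 5.89e-07), Lgals1 of -4.30 ± 0.32 (1.83e-07) and Cd36 of -2.83 ± 0.29 (8.35e-06), while Rnf128 had 3.36 ± 0.35 (9.79e-06). Over 17 endothelial genes the median difference was -1.41 (camera adjusted p = 1.38e-14), the only list with adjusted p under 0.05 with an estimated correlation (0.0385), which became 0.167 with mouse as a replicate block. Adipocyte genes (19, median -0.98, 5.57e-07) and lipid droplet genes (20, median -1.03, 1.06e-05) had adjusted p = 0.0896 with an estimated correlation, and macrophage genes (31, median 1.04, 2.11e-07) had 0.332. Of 10119 genes 538 had a higher effect in fat and 748 a higher effect in liver. The count of 1286 was 763 without the adipose array of KO mouse 429. The Actb 3'/5' log2 ratio on HFD was 0.73 ± 0.10 (SD) on KO and 1.44 ± 0.28 on WT arrays in fat, and 1.70 ± 0.01 and 2.04 ± 0.05 in liver, so RNA quality or labelling was not separated from the difference between tissues. With r = 0.21 across genes, 113 genes were higher in KO mice in both tissues on HFD, against 41.4 for independent lists, 53 were lower in both, against 34.7, and 57 were opposite, again with both tissues from the same mice.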

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

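The tests of the genes on other chromosomes, of the genes nearest to Ffar4, of chromosome 19 in each tissue, of genes with a single probe set, of pieces of epididymis, of batch, of adipocyte share, of RNA quality, of liver material and of mice 427 and 547 were chosen only after the result was seen. That of chromosome 19 was set before any value was seen, and the bounds for other probe sets, for mice 427 and 547 and for other splits were set after the gene calls were seen but before these tests were run.

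Differences between groups stood out in the interactions and between the tissues. In adipose tissue the diet effect differed between genotypes for 1273 genes, most clearly by p for Adgrl4 (-2.42 ± 0.23), Cyyr1 (-2.47 ± 0.24) and Tm4sf1 (-1.71 ± 0.17), which rose on HFD in WT fat by 2.58, 2.37 and 2.12. In liver it differed for 110 genes, with Orm2 at 6.19, Lcn2 at 4.22 and Cyp4a31 at -1.61 ± 0.17. The genotype effect on HFD differed between the tissues for 1286 genes, with Mogat1 at -5.99, Lgals1 at -4.30 and Cd36 at -2.83. Probe sets with no symbol or with several symbols also changed between KO and WT mice on HFD: 540.0 of 3057 in adipose tissue (186 higher, 354 lower) and 161 of 3285 in liver (50 higher, 111 lower).

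Other splits of the same arrays were counted for each comparison. For the comparisons of 3 against 3 arrays only 10 splits exist, too few for a share under 0.05, and 1 of 10, the real one, gave as many genes. In adipose tissue the real count and the highest other were 2612 and 90.0 for KO versus WT on HFD, 29 and 0 on ND, 6423 and 1 for diet in WT, and 5654 and 1 for diet in KO mice. In liver they were 747 and 0, 524 and 1, 1392 and 0, and 1839 and 1, and for the difference between tissues 1286 and 23. For the interactions and averages 100 splits were drawn and 1 of 100, the real one, gave as many. That is a share under 0.05, so a genotype without any effect is unlikely but not excluded. These splits cannot decide on an interaction or an average by itself. The other splits mix KO and WT arrays within groups, so genotype differences of either kind widen the spread there and lower their counts. The counts were 1273 against at most 677 and 1254 against 822 in adipose tissue, and 110 against 43 and 1290 against 54 in liver. The split that exchanges the genotype names on 1 diet was left out after a first run, because it turns the interaction into the average. It turns the average into the interaction as well. With it the highest other count for the interaction was 1254 in adipose tissue and 1290 in liver, and for the average 1273 and 110, so that for the adipose average and the liver interaction 2 of 100 splits were as large, the real one included.

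The first pattern weighed is the group of 142 genes that differed between KO and WT mice in both tissues. A candidate explanation is a chromosome segment of the 129 strain carried along with the targeted gene, and the share on chromosome 19 was above that of all tested genes (1-sided Fisher's exact test p = 0.0158), with 6 of the 100 nearest tested genes changed (p = 0.00282) and 5 of the 272 others (p = 0.312). In each tissue alone the enrichment of called genes on this chromosome had Fisher's exact p = 0.00215 in liver and 0.233 in adipose tissue. The segment leaves 131 of the 142 genes, on other chromosomes, without account. No other chromosome was tested for a higher share of these genes, so whether they group elsewhere was not examined. Strain variants under single probe sets would not carry to the others, and 68 of 83 other probe sets (81.9%, exact 95% interval 72.0 to 89.5%, which treats probe sets as independent) had the same sign in both tissues. These belong to 54 of the 142 genes, 41 of which had the same sign in every other probe set, and they speak against variants as the whole cause in these genes only. The other 88 genes had no further probe set above the filter, so there variants and a change of expression cannot be told apart, and Taf15, Gosr1, Vamp3 and Nudt9 lost the call in both tissues with the mean of their probe sets. Xaf1, also among the 142 genes (-0.66 in fat and -0.84 in liver), turned sign with that mean. It was then called higher in KO mice in fat (1.76, adjusted p = 0.000449) and in liver (1.18, 0.00712), so its direction depends on the probe set. Other differences of background between KO and WT mice were not tested and may add to the genes on other chromosomes, as may the loss of the receptor itself.

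The second pattern is the epididymis transcripts in fat of ND mice. Pieces of epididymis in these samples are a candidate explanation, since all 19 list genes on the array, or 100%, were higher on ND in both genotypes, by log2 2.31 or more. The test was first run on the 17 genes kept by the filter, which their ND values had let pass, and now covers the list, fixed beforehand, without a filter. It still restates what prompted it. A batch of arrays or labelling that went with diet was tested in the liver of the same mice. The test as first written asked for a median change within 0.5 of 0 in both genotypes to exclude it or below -1 to support it. The changes were -1.27 in WT and -0.32 in KO mice. By this rule it went with batch in WT mice alone and did not exclude it. The median log2 level of these genes over the liver arrays was 3.12, under the filter of 3.69. The liver changes were thus measured near the floor and decide neither way. A comparison of levels was then added, after these changes were seen, and only this speaks against it: the genes had a median log2 level of 3.49 (quartiles 2.20 to 4.11) in ND liver against 10.78 (9.56 to 12.52) in ND fat. A change of dissection between the diets and a change of the fat pad itself were not told apart.

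The third pattern is the rise of macrophage and fall of endothelial genes in KO fat on HFD. A smaller share of adipocytes would raise endothelial with macrophage transcripts, yet the upper quartile of the endothelial changes was -1.02. This value restates the fall that defines the pattern. It speaks only against a smaller adipocyte share by itself, and other changes in the shares of cell types were not tested. Other tissue in mice 427 and 547 was tested by leaving both arrays out, after which at least 116.9% of each median was left (macrophage 129.4%). RNA quality remains a candidate explanation: the Actb 3'/5' log2 ratio was lower by -0.71 on KO arrays, and since the KO arrays (0.62 to 0.80) and WT arrays (1.13 to 1.68) did not overlap, no arrays of like ratio could be compared. The higher median of hepatocyte genes raised the question of liver material in KO fat. It would lower macrophage genes, whose level in KO liver was below that in WT fat (upper quartile of the log2 differences -0.32). The endothelial fall would need a share of liver over 50%, yet hepatocyte genes lay at least 4.40 lower in KO fat than in KO liver for 75% of genes. A source of the hepatocyte transcripts themselves was not tested. The pattern is therefore not called biological, since RNA quality stays open.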

How the results depend on the processing

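The settings that leave out mice 427 and 547, or 686 and 690, were chosen after the data were seen. Genes changed when 1 array was left out numbered 1569 to 2679 for KO versus WT on HFD, 7 to 408 on ND, 5631 to 6095 for diet in WT, 4449 to 5554 for diet in KO mice, 639 to 1530.0 for the interaction and 663 to 1527 for the average in adipose tissue. In liver they numbered 274 to 681, 194 to 564, 672 to 1388, 1128 to 1305, 35 to 120 and 755 to 1309, and for the difference between tissues 763 to 1410.0. The difference between tissues, the only one fitted over both tissues, was also fitted with mouse as a replicate block. It then held 1033 genes, 915 of them shared with the 1286, 371 lost and 118 gained. The 4 genes named for it kept their calls (adjusted p at most 0.00101). Of 14 lists passing camera 12 passed with the block, and male-biased liver genes (0.0882) and inflammatory genes (0.0654) did not. With an estimated correlation 0 passed (endothelial genes 0.167). No other fit covered both tissues, so the block was run for no other result.

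Counts moved by over 1.5 times elsewhere as follows, and the cause was not tested. Quantile normalization gave 83 for adipose KO versus WT on ND. The mean of a gene's probe sets gave 18 there, 848 for the adipose interaction, and in liver 309 for KO versus WT on ND, 846 for diet in WT, 52 for the interaction and 745 for the average. The compared groups' arrays alone gave 9 in adipose and 331 in liver for KO versus WT on ND, and 622 for diet in WT liver. No filter gave 57 for the liver interaction. Without mice 686 and 690, 2 genes were left in adipose KO versus WT on ND, 382 in the interaction and 354 in the average, and the cell cycle list turned to higher on ND (adjusted p = 0.143). This setting left 1 WT ND array, so its counts do not show dependence on sperm transcripts. With the mean of probe sets signs turned for Xaf1 (1.87 in adipose KO versus WT on HFD and 1.76 averaged, 0.30 in liver on ND and 1.18 averaged), Tnfaip3 (-0.59, adipose diet in WT), Enho (-0.18, liver diet in WT) and Cyp27a1 (0.14, liver diet in KO mice). After quantile normalization uncalled Fabp4 in adipose KO versus WT on HFD turned to 0.0212. Ighm in the liver average ran from -0.90 without mouse 687 to 0.17 without mouse 428.

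Of 153 list calls by camera, fry kept 108 and an estimated correlation kept 0, apart from the endothelial list of the tissue difference without a block. Signal over background limited genes near the floor, whose changes are bounds, and 3 arrays per group limited 1.5-fold changes, of which simulation recovered 9.09 to 56.7%.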

Other observations

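The genes in this part were picked after their values were seen, from comparisons planned earlier. In KO fat on HFD, Plin5, a droplet protein (-2.48 ± 0.30), Mogat1 (-2.23 ± 0.33) and Pck1 (-2.20 ± 0.33) fell, while Mogat1 rose in liver (3.77 ± 0.35). Their lists did not pass in fat: lipid droplet genes rose in 2 and fell in 6 of 20 (2 and 7 over the list alone, camera adjusted p = 0.192, 0.63 with an estimated correlation), and gluconeogenesis genes rose in 1 and fell in 3 of 11 (1 and 4 over the list alone, 0.103, 0.437). The interaction with diet was negative for Pck1 (-3.23), Plin5 (-2.56) and G0s2, an inhibitor of lipolysis (-2.51). The mast cell protease gene Cpa3 rose (2.34 ± 0.42), and so did Itgax (3.11 ± 0.41) and Saa3 (3.51 ± 0.78).

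In KO liver on HFD, Gstm3 (3.20 ± 0.45) and Gstm2 (2.05 ± 0.22), of glutathione conjugation, rose, Igfbp2 fell (-1.77 ± 0.21), and the bile acid enzyme gene Cyp7b1 fell (-1.25 ± 0.24).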
